A study of Mus musculus with 26 samples.

How the data were processed

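Gene expression was measured in 26 mouse samples, each on its own array: 3 cultures of osteoblasts differentiated in vitro, which the series uses as its control, 15 primary osteosarcomas, 4 osteosarcoma cell lines and 4 secondary tumours. Osteosarcoma is a malignant bone tumour of the osteoblast lineage. Groups were taken from the labels. Of the 4 secondary tumours, those numbered 29, 64 and 94 are labelled as transplants of a tumour, and the one numbered 66 is labelled as tumour tissue grown from a cell line. The title of number 66 calls it a cell line, and it was kept with the secondary tumours. Tumour numbers were taken from the labels; the osteoblast cultures are numbered 1 to 3 there. The labels do not say that the osteoblast cultures came from separate animals, so the spread between these cultures may be technical. Tests against them use a spread pooled over all 4 groups, so their p-values do not show how far osteoblasts of other animals would vary.

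Per the labels' protocols, RNA was reverse transcribed from its poly(A) end, copied into biotin-labelled cRNA by T7 polymerase and hybridised to 1-colour oligonucleotide arrays. The deposited values are intensities on a linear scale, 1 per probe set, for 45101 probe sets of which 64 are controls. The software and the steps by which the authors summarised probes, corrected background and scaled the arrays are not given in the sources used here. The values ran from 0.497 to 21734, and 15834 of them (1.35%) were exactly 1. Array medians lay between 44.4 and 58.8. Because these were close, the arrays were taken as already scaled to each other and used as deposited, although they did not share a common distribution. No array was a copy of another: the most alike pair, osteoblast cultures 1 and 2, had a correlation of 0.991 and shared 0.574% identical values.

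Probe sets were named from the platform's annotation, with symbols updated by gene identifier through a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of the probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 were unnamed here; 34754 matched a gene identifier in the table. No genome coordinates were used. Some genes of the lists below were not named by the annotation used here: 272 of 337 list genes, and 7 of the 10 genes that the naming rule always includes, were measured.

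The main settings were fixed before the data were examined. Linear intensities were raised to a floor at the 20th percentile of all values, an intensity of 12.5 or 3.64 on the log2 scale, and then taken to log2 without further normalization. A probe set was kept when at least 3 of the 26 arrays lay above the median of all values, an intensity of 52.6, which left 27344 probe sets. Each gene was represented by its kept probe set with the highest mean over all arrays, which gave 12887 genes. Other probe sets of a gene can differ from the chosen one. A value at the floor gives only a bound, so a difference against a group whose arrays all lie at the floor is given as "at least". Over all probe sets, 18.6% to 23.3% of values on an array were at the floor. For arrays the number of samples limits the precision, and a group of 3 or 4 arrays gives a wide error.

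Each of 6 comparisons between the 4 groups was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes on log2 intensities), with all 26 arrays in one model and no covariate. p-values were adjusted by Benjamini-Hochberg over all genes of a comparison. A gene was called when its adjusted p was below 0.05 and its fold at least 2, which is 1 on the log2 scale. Every adjusted p printed for a gene comes from limma. Errors of log2 differences are limma's moderated standard errors (SE), and group values are means ± SD. The SE rests on a spread shared by all 4 groups, so it is too small where a small group varies more than the others.

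The 14 gene lists and 10 cell type marker lists, 24 in all, were fixed before the data were examined: osteoblast identity, mineralisation and osteocyte, cartilage, adipocyte, fibrous matrix, mitosis, S phase and E2F targets, genes induced in the DNA damage response, hypoxia and glycolysis, immediate early, interferon response, MHC class II, Wnt pathway and osteosarcoma-associated genes, and markers of macrophages, T and NK cells, B and plasma cells, neutrophils and myeloid precursors, erythroid cells, endothelium, skeletal muscle, osteoclasts, smooth muscle and pericytes, and sex-linked genes. Twist1 is in 2 lists. The list of genes induced in the DNA damage response was fixed as targets of the transcription factor p53, and its test speaks of these targets only. Each list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over all 144 tests. Of these, 36 passed. With the correlation estimated per list 3 passed, the adipocyte list in each comparison against osteoblasts, and none was gained. fry, which asks only whether the genes of a list move on balance one way, passed 55. For members, the count called over all genes is given beside the count adjusted over the list alone.

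Genes were named by a rule fixed before the data were examined. For each comparison it takes the called genes with the largest rises and falls whose groups do not overlap on any array (5 each way, or 3 each way where secondary tumours are compared), passing over unannotated transcripts, the measured members, at most 4, with the largest absolute difference in each list that passed, and in comparisons against osteoblasts the always-named genes Rb1, Cdkn1a, Cdkn2a, Mki67, Myc, Sp7 and Col1a1, called or not. Any other gene named was chosen after its values were seen, and the text says so.

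Tumour numbers shared between groups were tested as a pairing. Each cell line's and secondary tumour's deviation from its group mean was correlated, across 12887 genes, with the deviation of the primary tumour of the same number from the mean of the 15 primary tumours. The mean correlation was set against every other assignment in a one-sided exact permutation test. For the 4 secondary tumours the correlations were 0.449 (number 29), 0.302 (64), 0.224 (66) and 0.642 (94), all above 0.1, so the numbers were taken to pair secondary with primary tumours, and the fit with the tumour number as a block is given beside a result where it changes a call. For the cell lines every correlation was below 0.1.

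The arrays carry bacterial control transcripts. The ratios of the bioB to the bioC and of the bioD 5′ to the bioD 3′ controls parted the arrays into 3 hybridisation batches, a grouping made after the data were seen. Arrays with a first ratio above 0.566 formed batch C, and the others were parted at a second ratio of 0.535; each limit is the middle of the largest gap on the log scale. The labels give no hybridisation batch. Batch A holds the 3 osteoblast cultures. Batch B holds primary tumours 12, 29, 64, 66, 87, 94 and 119 and all 4 secondary tumours. Batch C holds primary tumours 176, 179, 182, 183, 188, 330, 331 and 353 and all 4 cell lines. Batch A has no other group, so batch and group cannot be told apart in any comparison against osteoblasts. The other comparisons were repeated with the batch as a term and, where 1 batch holds both groups, within it.

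Overlaps between comparisons that share the osteoblast arrays were set against the overlap of independent lists and against 100 simulations of unchanged groups that share those arrays. The osteoblast group has 3 arrays, so it could not be split into sets of at least 2. Comparison counts were also set against other splits of the same arrays, at most 100 and drawn at random where more exist.

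Each fit was tested on simulated data of 12887 genes, drawn with normal noise from each gene's real mean and residual spread, with 100 genes changed by 1 and 100 by 2 on the log2 scale. A gene was recovered when its adjusted p was below 0.05 with the right sign, without the fold minimum. Of the genes changed by 1, the all-array fit recovered 57% for primary tumours against osteoblasts, 50% for cell lines against osteoblasts, 52% for secondary tumours against osteoblasts, 67% for cell lines against primary tumours, 74% for secondary against primary tumours and 57% for cell lines against secondary tumours. Of the genes changed by 2 it recovered 95%, 90%, 91%, 96%, 95% and 90% in the same order, and 4 to 10 unchanged genes had an adjusted p below 0.05. The fit with the tumour number as a fixed block recovered 5% and 67% of genes changed by 1 and 2 for secondary against primary tumours. For cell lines against primary tumours it recovered 0% of both sizes, although 78% and 99% of them had an unadjusted p below 0.05, and 42.2% and 88.9% when 1500 genes of each size were changed. In such data a call lost under that block is by itself no sign of a smaller difference. Simulated arrays of the same tumour number shared no tumour effect, whereas same-numbered real samples had a consensus correlation of 0.353. How many changed genes the block recovers in real pairs was therefore not tested. Whether a difference shrinks under the block has to be read from its value there. In simulated data for primary tumours against osteoblasts with 1 shifted list, camera found that list and no other. Genes were simulated independently of each other, so this could not test the preset correlation. In the real data the estimated correlation reached 0.839 for the mitosis list.

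Alternatives fixed before the data were examined were quantile normalization, scaling to a common 75th percentile, floors at the 5th and 40th percentile, no filter and a filter at the 75th percentile, the mean of a gene's probe sets, every kept probe set, a model of only the groups compared, array weights per group, eBayes with trend and robust settings, no fold minimum, treat against a fold of 1.5, the tumour number as a fixed or a random block, each osteoblast, cell line or secondary tumour array left out in turn, an estimated correlation or fry for the lists, and other gene sets for the similarity. Alternatives added after the data were seen were primary tumours of batch B or of batch C alone, the batch as a term, the tumour-number block within batch B, similarity within a batch, and results without primary tumour 330. Means of lists written after the data were seen were compared between groups by exact permutation tests, and between tumours of the same number by an exact test that flips the sign of each pair's difference.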

Results

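Transcript levels were measured on 26 arrays: 3 of osteoblasts, the bone-forming cells, differentiated in culture, 15 of primary osteosarcomas, 4 of cell lines and 4 of secondary tumours. The array medians were 46.4 to 48.2 for osteoblasts, 44.4 to 48.2 for cell lines, 50.4 to 58.8 for primary tumours and 54.9 to 58.1 for secondary tumours, in intensity units. The ratio of the Gapdh 5′ to the Gapdh 3′ control probe set, which falls when RNA is degraded or copied short, was 0.916 to 0.967 in osteoblasts, 1.04 to 1.08 in cell lines, 0.656 to 1.03 in primary tumours and 0.839 to 1.08 in secondary tumours. Bacterial control transcripts added at hybridisation parted the arrays into 3 batches. The bioB to bioC ratio was 0.358 to 0.386 in batch A, 0.293 to 0.335 in batch B and about 0.83 to 0.948 in batch C. The bioD 5′ to 3′ ratio was 0.64 to 0.671, 0.347 to 0.448 and 0.511 to 0.693 in the same order. The osteoblast cultures form batch A alone, so in the comparisons against them batch and group cannot be told apart.

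**Figure D1:**
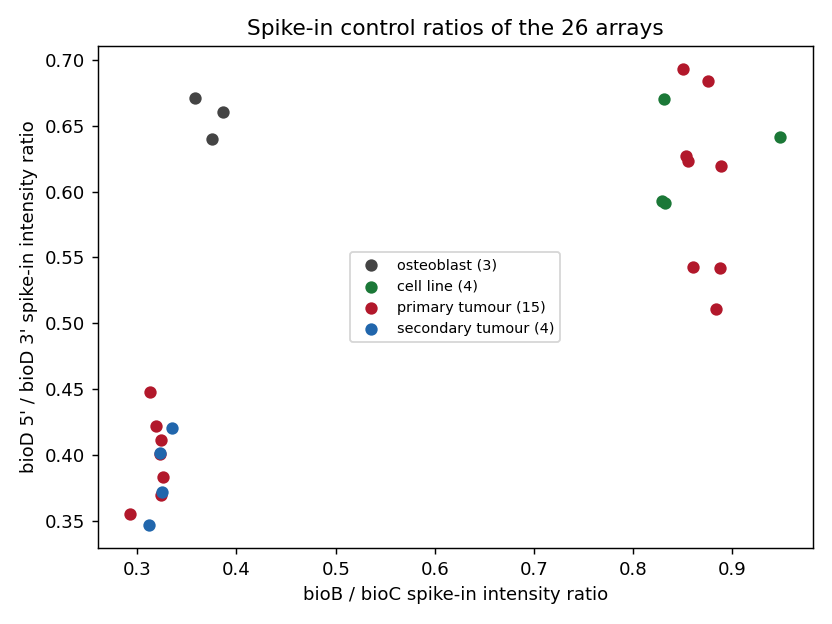
Ratio of the bioB to the bioC control intensity (horizontal axis, no unit) against the ratio of the bioD 5′ to the bioD 3′ control intensity (vertical axis, no unit), with 1 point per array coloured by group. The 12 arrays of batch C have a mean bioB to bioC ratio of 0.866, and all other arrays lie at 0.386 or less. Among the others the osteoblast arrays lie at a bioD ratio of 0.64 or more and the 11 arrays of batch B at 0.448 or less.

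The first comparison asked which genes separate primary osteosarcomas from cultured osteoblasts. Of the measured markers, 14 of 15 macrophage and 10 of 14 endothelial genes rose in the tumours, and all 8 fat cell genes fell. C1qa, a subunit of the complement protein C1q made by macrophages, was 10.73 ± 0.67 on the log2 scale (SD, n = 15) in primary tumours and at the floor in all 3 osteoblast cultures, at least 136-fold higher (limma adjusted p = 3.67e-13). Wif1, a secreted inhibitor of Wnt signalling, rose from 5.20 ± 0.31 (n = 3) to 11.74 ± 1.39 (log2 difference 6.54, SE 0.739, limma adjusted p = 1.87e-07). Adipoq, the fat cell hormone adiponectin, fell from 12.79 ± 0.05 to 4.42 ± 1.04 (log2 difference −8.37, SE 0.633, adjusted p = 2.09e-10). The other largest rises were in C1qc (6.18), C1qb (5.99) and Ctss (5.75), a protease of antigen-presenting cells. The other largest falls were in Egfl6 (−7.25), Penk, which encodes the opioid precursor proenkephalin (−6.62), the matrix protein gene Ccn3 (−6.50) and Hs6st2, a heparan sulfate sulfotransferase (−6.28). Here and below, the genes with the largest rises and falls were named among those whose groups did not overlap on any array. In all, limma called 2378 of 12887 genes, 848 higher and 1530 lower in primary tumours. Scaling to a common 75th percentile gave 1070 higher and 1305 lower and moved the median difference of all genes from −0.065 to 0.039. When every kept probe set was tested, 3011 were higher and 3042 lower.

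Of the 15 measured macrophage markers 14 rose, and 14 adjusted over the list alone (median log2 difference 3.93, camera adjusted p = 1.22e-14, and adjusted p = 0.228 with an estimated correlation). Tyrobp, a signalling adaptor of myeloid cells, rose by 4.50 (adjusted p = 9.28e-09). Of 6 MHC class II genes, which present antigen to T cells, 4 rose, and 4 adjusted over the list alone (median 2.50, adjusted p = 0.00203, and adjusted p = 0.448 with an estimated correlation). H2-Aa rose by 4.29, the invariant chain gene Cd74 by 3.94, H2-Eb1 by 2.64 and H2-Ab1 by 2.36. Of 14 endothelial markers 10 rose, and 10 adjusted over the list alone (median 1.53, adjusted p = 9.02e-06, and adjusted p = 0.448 with an estimated correlation), among them the VEGF receptor Kdr (2.66), Plvap (2.43), Esam (2.10) and the tight junction gene Cldn5 (1.74). Of 15 skeletal muscle markers 10 rose, and 13 adjusted over the list alone (median 3.18, adjusted p = 0.00133, and adjusted p = 0.694 with an estimated correlation). The myosin heavy chains Myh1 and Myh2 rose by 5.19 and 4.79, the myosin light chain Mylpf by 4.56, and the troponin Tnnc2, at the floor in all osteoblast arrays, was at least 4.32 higher. The mean of the muscle markers ran from 4.81 to 10.56 among the primary tumours.

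All 8 measured adipocyte genes fell in primary tumours, and 8 adjusted over the list alone (median −4.28, camera adjusted p = 1e-08), and this call held with an estimated correlation (adjusted p = 0.0382). The list mean was 10.89 in the osteoblast cultures and at most 7.23 on any other array. In every comparison against osteoblasts, a high level in these cultures therefore cannot be told apart from a fall in the tumours or lines. The fatty acid carrier Fabp4 changed by −5.48, the lipase Lpl by −4.38, and Pparg, the regulator of fat cell differentiation, lay at the floor in all 15 primary tumours and was at least 37.4-fold lower. Of 16 hypoxia and glycolysis genes 5 fell, and 5 adjusted over the list alone (median −0.71, adjusted p = 0.0211, and adjusted p = 0.694 with an estimated correlation). These included the vasodilator peptide gene Adm (−4.03), the mitophagy receptor Bnip3 (−1.67), the carbonic anhydrase Car9 (−1.52) and the collagen prolyl hydroxylase P4ha1 (−1.19). Of 17 genes induced in the DNA damage response, chosen as p53 targets, 3 fell, and 3 adjusted over the list alone (median −0.55, adjusted p = 0.0388, and adjusted p = 0.448 with an estimated correlation). They were the death receptor Fas (−3.81), the cyclin Ccng1 (−2.56) and Phlda3 (−1.60), while the difference for Perp was 2.01 (adjusted p = 0.0846). Of 21 S phase genes 3 rose and 1 fell, with the same counts adjusted over the list alone (median 0.56, adjusted p = 0.0128, and adjusted p = 0.694 with an estimated correlation). The replication licensing genes Cdt1, Mcm2 and Mcm3 rose by 1.13, 1.03 and 1.02, and Cdc6 changed by −1.42.

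Among the genes named in every comparison against osteoblasts, Cdkn2a, an inhibitor of cell cycle kinases, rose by 2.30 in primary tumours (adjusted p = 0.000131), and Sp7, a transcription factor needed for osteoblast formation, by 1.67 (adjusted p = 0.0348). The differences for Rb1, which restrains entry into S phase (0.17, adjusted p = 0.724), the kinase inhibitor Cdkn1a (−0.55, 0.418), the proliferation marker Mki67 (0.25, 0.564), Myc (0.10, 0.725) and the main bone collagen Col1a1 (0.09, 0.426) did not pass. The call of Sp7 was lost without any 1 of the osteoblast cultures (1.59, 1.64 and 1.78 without cultures 1, 2 and 3), as was that of Tnnc2 (at least 4.32 without any of them). So were those of Mylpf without cultures 1 (4.48) or 3 (4.32), Cdc6 without culture 2 (−1.37), Mcm2 without culture 3 (0.998) and Mcm3 without primary tumour 330 (0.974). With primary tumours of batch B alone the S phase list (median 0.60) and the DNA damage response list (−0.58) no longer passed, the latter also not without primary tumour 330 (−0.55). With those of batch C alone the hypoxia list (−0.66), Sp7 (1.44) and Mcm2 (0.99) did not. The filter at the 75th percentile ended the calls of the hypoxia (−0.65) and DNA damage response (−0.60) lists, and fry that of the S phase list. The mean of the gene's probe sets ended those of Mcm2 (0.93) and Mcm3 (0.80), and quantile normalization that of P4ha1 (−0.89). Without the filter on dim probe sets Sp7 (1.67) was not called, nor with the floor at the 40th percentile Tnnc2 (at least 3.10). Perp was called with array weights (2.01) and with primary tumours of batch B (1.96).

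**Figure D2:**
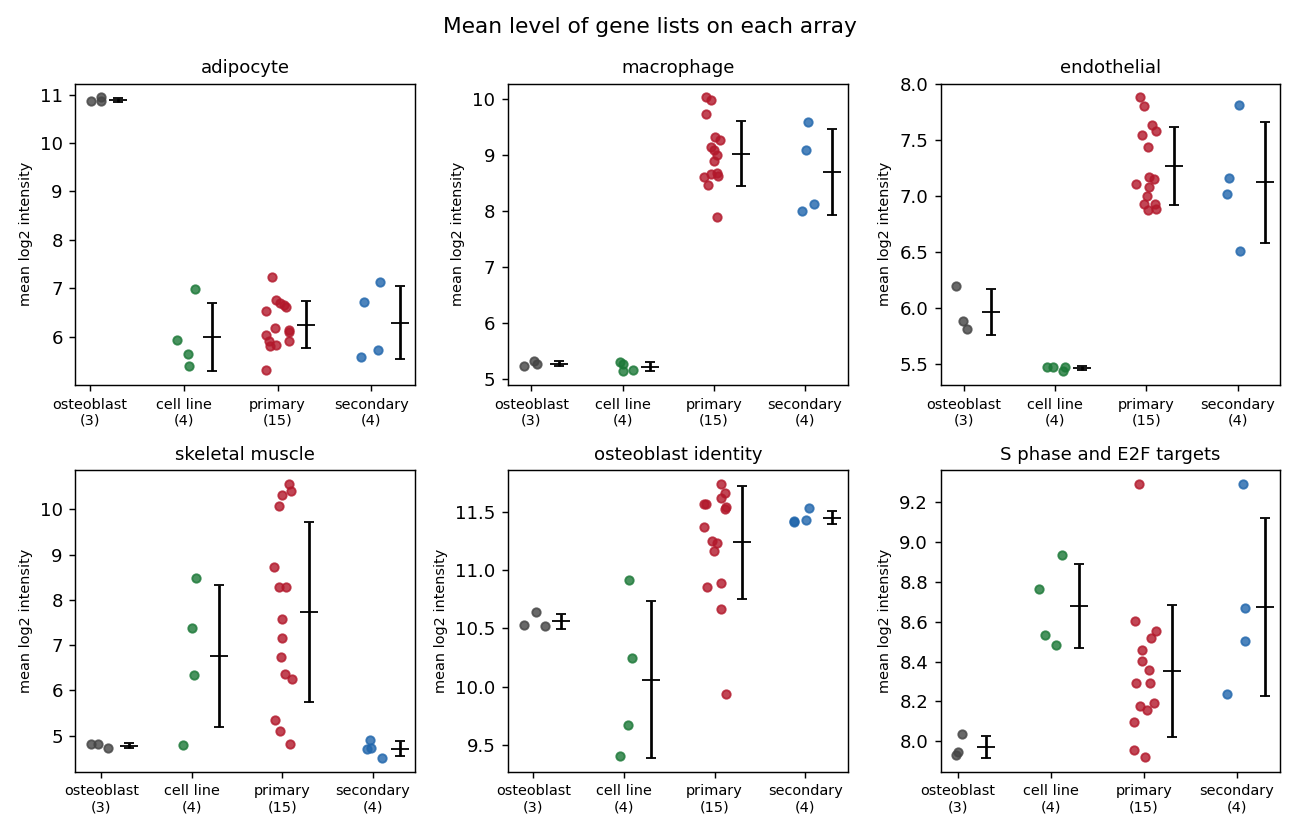
Mean log2 intensity (vertical axes) of the measured genes of 6 lists on each array, with arrays grouped as osteoblasts (3), cell lines (4), primary tumours (15) and secondary tumours (4). Points are arrays, and the bar beside them is the group mean ± SD. The adipocyte mean was 10.89 in osteoblasts and at most 7.23 on any other array, and the macrophage mean was at least 7.89 in every primary and secondary tumour and at most 5.32 in every osteoblast culture and cell line.

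Cell lines were compared with osteoblasts to ask which genes set osteosarcoma cells in culture apart. All 8 measured fat cell genes, 6 of 12 cartilage genes and 4 of 17 fibrous matrix genes fell in the lines. The Gapdh 5′ to 3′ ratio was 1.04 to 1.08 in the lines and 0.916 to 0.967 in the osteoblasts. Ifi202b, an interferon-inducible gene, rose from 3.73 ± 0.16 (SD, n = 3) to 9.68 ± 0.57 (n = 4), a log2 difference of 5.95 (SE 0.539, limma adjusted p = 1.78e-08). Adipoq fell from 12.79 ± 0.05 to 4.06 ± 0.85 (log2 difference −8.73, SE 0.765, adjusted p = 1.05e-08). The next largest rises were in the troponin Tnnc1 (3.64), the actin regulator Cap1 (3.62), Mymk, needed for the fusion of muscle cells (3.48), and Popdc3 (3.46). The lines differed in these muscle genes: Tnnc1, Mymk and Popdc3 had SDs of 2.64, 2.07 and 1.74 among the 4 lines and rose by 4.76, 4.40 and 4.24 without cell line 176. Without cell line 179 Tnnc1 and Mymk rose by 2.69 and 2.81. The next largest falls were in Wfdc21 (−7.19), Fabp4 (−7.19), the carbonic anhydrase Car3 (−6.93) and Penk (−6.55). In all, 1059 genes were called, 203 higher and 856 lower, and 420 and 1588 when every kept probe set was tested. The share of higher calls was 19.2%, against 30.4% after quantile normalization and 35.1% after scaling to a common 75th percentile, which moved the median difference of all genes from −0.10 to 0.06 and 0.08.

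All 8 adipocyte genes fell in the cell lines, and 8 adjusted over the list alone (median −4.11, camera adjusted p = 1.38e-14), and the call held with an estimated correlation (adjusted p = 0.00566). The fatty acid transporter Cd36 changed by −5.81 and the transcription factor Cebpa by −4.21. Of 12 cartilage genes 6 fell, and 6 adjusted over the list alone (median −1.75, adjusted p = 2.28e-05, and adjusted p = 0.112 with an estimated correlation), among them the matrix protein gene Comp (−5.95), the lubricin gene Prg4 (−5.80), the link protein gene Hapln1 (−3.49) and Cnmd, at the floor in all 4 lines and at least 30.5-fold lower. Of 17 fibrous matrix genes 4 fell, and 4 adjusted over the list alone (median −0.48, adjusted p = 0.0461, and adjusted p = 0.694 with an estimated correlation). They were the proteoglycans Lum (−5.26) and Dcn (−2.76), Thbs1 (−2.72) and Mgp, an inhibitor of calcification (−2.20). Of 21 S phase genes 5 rose, and 5 adjusted over the list alone (median 0.76, adjusted p = 6.44e-07, and adjusted p = 0.448 with an estimated correlation), with Cdt1 at 1.89, the transcription factor E2f2 at 1.71, Mcm2 at 1.42 and Mcm3 at 1.20. Of 17 genes induced in the DNA damage response 6 fell, and over the list alone 6 fell and 1 rose. Their median was −0.75, and the list did not pass (camera adjusted p = 0.0592, and 0.467 with an estimated correlation), although it passed with fry (adjusted p = 0.000192).

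The 15 skeletal muscle markers passed as a list in the cell lines (median 1.40, adjusted p = 0.00511, and adjusted p = 0.713 with an estimated correlation), although 0 of them passed singly, over all genes or adjusted over the list alone. The largest differences were in Mylpf (4.82, adjusted p = 0.0716), Tnnc2 (at least 26.4-fold, since all osteoblast arrays lay at the floor, 0.0884), Tnnt3 (3.49, 0.154) and Myh1 (3.41, 0.194). Cdkn2a rose by 3.21 (adjusted p = 0.000107). Col1a1 differed by −0.36 (adjusted p = 0.0292), below the fold minimum, and Rb1 (−0.07, 0.941), Cdkn1a (−0.18, 0.894), Mki67 (−0.33, 0.635), Myc (0.42, 0.292) and Sp7 (−0.50, 0.716) did not pass. The muscle list (2.34 without cell line 176, 0.87 without 179) no longer passed after quantile normalization (1.29) or 75th percentile scaling (1.58), or with fry. The fibrous matrix list (−0.72 without 182, −0.20 after quantile normalization) did not without cell line 176 (−0.34) or 213 (−0.51), without osteoblast culture 2 (−0.52) or 3 (−0.50), or without secondary tumour 29, which enters the shared spread (−0.48). The calls of Mgp and E2f2 were lost without any 1 osteoblast culture (−2.12 to −2.27 for Mgp and 1.63 to 1.79 for E2f2). That of Mgp was also lost without cell line 176 (−1.31), and that of E2f2 without cell line 179 (1.35), 182 (1.64) or 213 (1.78), while Mylpf (6.29) and Tnnc2 (at least 6.30) were called without cell line 176. The lowest differences over all alternatives were 3.815 for Mylpf and 3.66 for Tnnc2. The floor at the 40th percentile, the filter at the 75th percentile and the mean of the gene's probe sets each ended the call of the fibrous matrix list (median −0.48 in each). Mgp was not called after quantile normalization (−2.00) or 75th percentile scaling (−2.02), without the filter or with only both compared groups in the fit (−2.20 in each). E2f2 was not after quantile normalization (1.67) or without the filter (1.71), nor Tnnc1 with only both groups in the fit (3.64). With array weights Mylpf, Tnnc2, Tnnt3 and Myh1 were called. Without cell line 182 Comp was at −6.66, and without 213 Fabp4 at −8.07.

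Secondary tumours were also set against osteoblasts. Of the measured markers, 12 of 15 macrophage, 8 of 14 endothelial and 5 of 6 MHC class II genes rose, and all 8 fat cell genes fell. Wif1 rose from 5.20 ± 0.31 (SD, n = 3) to 12.19 ± 0.51 (n = 4), 128-fold higher (SE of the log2 difference 0.892, limma adjusted p = 2.17e-06). C1qa, at the floor in the osteoblasts, was at least 96.0-fold higher (adjusted p = 1.15e-10), and Tbx1, a transcription factor of the pharyngeal region, rose from 3.65 ± 0.02 to 9.46 ± 0.52 (5.81, SE 1.15, adjusted p = 0.000408). Tbx1 lay at or just above the floor in the osteoblasts, so its difference is close to a bound. It ran from 4.40 to 6.36 over the alternatives. The largest falls were in Adipoq (−7.52, SE 0.765, adjusted p = 6.8e-08), Egfl6 (−7.34) and Comp (−6.85). The value of Egfl6 is close to a bound, since it was 3.73 in secondary tumour 64 and at the floor in the others. limma called 2381 genes, 993 higher and 1388 lower. When every kept probe set was tested the balance turned, with 3510 higher and 2731 lower.

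Of 15 macrophage markers 12 rose in secondary tumours over all genes and 13 adjusted over the list alone (median 3.55, adjusted p = 7.26e-13, and adjusted p = 0.257 with an estimated correlation), with C1qc at 5.79, C1qb at 5.74 and the growth factor receptor Csf1r at 4.28. Of 6 MHC class II genes 5 rose, and 5 adjusted over the list alone (median 3.91, adjusted p = 6.29e-05, and adjusted p = 0.295 with an estimated correlation), with H2-Aa at 5.69, Cd74 at 5.24, H2-Eb1 at 3.98 and H2-Ab1 at 3.83. Of 14 endothelial markers 8 rose, and 8 adjusted over the list alone (median 1.31, adjusted p = 0.000234, and adjusted p = 0.643 with an estimated correlation), with Kdr at 2.26, the junction cadherin Cdh5 at 2.10, Cldn5 at 2.02 and Esam at 1.92. All 8 adipocyte genes fell, and 8 adjusted over the list alone (median −4.50, adjusted p = 2.34e-09), a call that held with an estimated correlation (adjusted p = 0.0382). Fabp4 changed by −5.40 (−6.08 without secondary tumour 64), Pparg by −5.17 and Cd36 by −4.53. Of 17 DNA damage response genes 3 fell, and 3 adjusted over the list alone (median −0.77, adjusted p = 0.0146, and adjusted p = 0.351 with an estimated correlation). These were Fas (−3.80), Ccng1 (−2.34) and Phlda3 (−1.83), and the 2.83-fold higher level of Perp did not pass (adjusted p = 0.314).

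Of 19 mitosis genes 4 rose in secondary tumours, and 4 adjusted over the list alone (median 0.66, adjusted p = 0.0228, and adjusted p = 0.833 with an estimated correlation). The spindle gene Nusap1 rose by 1.72, the mitotic kinase Aurka by 1.32 and the kinetochore motor Cenpe by 1.26, and the motor Kif11 stood at 1.34 (0.0827). Of 21 S phase genes 6 rose, and 6 adjusted over the list alone (median 0.79, adjusted p = 0.000381, and adjusted p = 0.694 with an estimated correlation), among them the histone methyltransferase Ezh2 (1.53), Cdt1 (1.28), Mcm2 (1.26) and the transcription factor Mybl2 (1.13). Cdkn2a rose by 2.93 (adjusted p = 0.00012) and Sp7 by 2.06 (0.0376). Rb1 (0.35, 0.551), Cdkn1a (−1.23, 0.14), Mki67 (0.66, 0.21), Myc (0.15, 0.69) and Col1a1 (0.00, 0.989) did not pass. The mitosis list (0.47), Aurka (1.05), Cenpe (1.02) and Mybl2 (0.94) were not called without secondary tumour 29, Cenpe not without 94 (1.23), and Sp7 not without 29 (2.01), 64 (1.90) or 66 (2.13). Without osteoblast culture 1, 2 or 3 Sp7 (1.98, 2.02 and 2.17) lost its call, as did Aurka without cultures 1 (1.24) and 2 (1.32), Cenpe without 1 (1.27) and 3 (1.15) and Mybl2 without 3 (0.94). Mybl2 was also not called after quantile normalization (0.87) or as the mean of its probe sets (0.95), nor Sp7 without the filter on dim probe sets (2.06), and the mitosis list did not pass with fry. Kif11 was called as the mean of its probe sets (1.38), with only both groups in the fit and with array weights, and Cdkn1a with array weights (−1.23).

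The genes called against osteoblasts were compared between the tumour groups. In all 3 comparisons 61 genes were higher, led by Ifi202b, Cap1, the transcription factor Runx3, Cdkn2a and Gatm, and 506 were lower, led by Adipoq, Egfl6, Wfdc21, Penk and Comp. Runx3 rose by 3.54 in primary tumours, 2.21 in cell lines and 3.23 in secondary tumours, and it and Gatm were chosen after their values were seen. Primary and secondary tumours shared 1872 calls in the same direction, 695 higher and 1177 lower, with 0 in opposite directions. Independent lists would share 65.3 and 165, and 100 simulations of unchanged groups against the same osteoblast arrays shared 0.06 genes on average and at most 5. Primary tumours and cell lines shared 73 higher and 578 lower genes, with 10 opposite, where independent lists would share 13.4 and 102 and the simulations shared 0. Cell lines and secondary tumours shared 69 higher and 528 lower genes, with 13 opposite, where independent lists would share 15.6 and 92.2 and the simulations shared 0. Across genes, which are not independent replicates, the log2 differences of primary and secondary tumours had a correlation of 0.941 and a covariance of 0.988, where simulated unchanged groups gave 0.688 and 0.0826, a covariance difference of 0.906. For primary tumours and cell lines the correlation was 0.633 (simulated 0.691) and the covariance 0.498 (0.0834), a difference of 0.414. For cell lines and secondary tumours these were 0.583 (0.57) and 0.476 (0.0852), a difference of 0.391. Part of the excess over independent lists may come from the shared osteoblast arrays, which were too few to split. The simulated counts cannot show how large this part is, because unchanged groups give hardly any calls that could be shared. All 4 secondary tumours also carry the number of a primary tumour and were taken as paired with it. Primary and secondary tumours are therefore not independent groups, and the simulations carried no such pairing.

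Cell lines were compared with primary tumours to ask what differs between tumour tissue and cultured tumour cells. Of the measured markers, 14 of 15 macrophage, 9 of 14 endothelial, 4 of 6 MHC class II and 6 of 12 osteoblast identity genes fell in the lines. Wif1 fell from 11.74 ± 1.39 (SD, n = 15) to 4.73 ± 1.38 (n = 4), a log2 difference of −7.01 (SE 0.657, limma adjusted p = 3.08e-08), and C1qa from 10.73 ± 0.67 to 3.78 ± 0.21 (−6.95, SE 0.339, adjusted p = 4.56e-13). Among the largest falls were also C1qc (−6.74), the lysozyme gene Lyz1 (−6.62) and Ctss (−6.12). The largest rises were in the pentraxin Ptx3, from 5.86 ± 1.07 to 9.78 ± 0.32 (3.92, SE 0.489, adjusted p = 2.07e-06), Ccn5 (3.84), the glutamate transporter Slc1a3 (3.39), the tissue factor gene F3 (3.23) and Eya4 (3.21). limma called 1514 genes, 608 higher and 906 lower. The split was 747 and 754 after quantile normalization, 746 and 803 after 75th percentile scaling, and 1234 and 2946 when every kept probe set was tested. Against the primary tumours of batch C, the batch of the lines, 1294 genes were called, 1137 of them among the 1514. The Gapdh 5′ to 3′ ratio was 1.04 to 1.08 in the lines and 0.909 to 1.03 in those primary tumours. With the batch as a term 1278 were called, 1124 of them among the 1514.

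Of 15 macrophage markers 14 fell in cell lines, and 14 adjusted over the list alone (median −4.12, adjusted p = 1.77e-16, and adjusted p = 0.216 with an estimated correlation), with C1qb at −5.96 and the mannose receptor Mrc1 at −5.06. Of 14 endothelial markers 9 fell, and 9 adjusted over the list alone (median −1.76, adjusted p = 4.21e-09, and adjusted p = 0.269 with an estimated correlation), with Cdh5 at −4.02, Plvap at −3.04, Esam at −3.03 and the adhesion molecule Pecam1 at −2.81. The value of Pecam1 is in effect a bound, since to the printed digits it lay at the floor in all lines (3.64). Of 6 MHC class II genes 4 fell, and 4 adjusted over the list alone (median −2.93, adjusted p = 0.000219, and adjusted p = 0.354 with an estimated correlation), with Cd74 at −4.06, H2-Aa at −3.57, H2-Eb1 at −3.03 and H2-Ab1 at −2.83. Of 12 osteoblast identity genes 6 fell, and 6 adjusted over the list alone (median −1.21, adjusted p = 0.000319, and adjusted p = 0.448 with an estimated correlation), with the alkaline phosphatase Alpl at −2.70, the parathyroid hormone receptor Pth1r at −2.42, Sp7 at −2.17 and Fgfr2 at −1.46. Of 13 interferon response genes 5 rose, and 5 adjusted over the list alone (median 1.10, adjusted p = 0.0116, and adjusted p = 0.715 with an estimated correlation), with the virus-tethering protein gene Bst2 at 3.24, Usp18 at 2.48, Ifit1 at 2.43 and Ifit3 at 1.83. The interferon list did not pass in the lines against osteoblasts (0 of 13 called, median 0.21, camera adjusted p = 0.23). In primary tumours 5 of its genes were lower than in osteoblasts and 1 higher (median −1.42, camera adjusted p = 0.402). Its mean was 7.89 in osteoblasts, 8.04 ± 1.74 (SD) in the lines and 6.77 in primary tumours. Primary tumours had 5 osteoblast identity genes higher than osteoblasts (camera adjusted p = 0.124), and the lines had 1 lower (0.168). Against primary tumours of batch C the medians were −4.07 for macrophage, −1.68 for endothelial, −2.60 for MHC class II, −0.83 for osteoblast identity and 1.37 for interferon genes, and each list still passed. The interferon list (1.85 without cell line 176) did not pass without cell line 179 (0.85) or 213 (0.87) or against primary tumours of batch B (0.86). Ifit1 (adjusted p = 0.0492, and 4.12 without cell line 176) was not called without cell line 179 (1.75), 182 (2.04) or 213 (1.83), nor without any 1 of the osteoblast or secondary tumour arrays, which enter the shared spread. Usp18 was not without 179 (1.98) or 213 (1.92). Ifit1 was also not called without the filter on dim probe sets, with only both groups in the fit, against primary tumours of batch B (1.95) or with the batch as a term (2.86), and the interferon list did not pass with fry. Without cell line 176 the differences were larger in Bst2 (4.17), Usp18 (3.64), Ifit3 (2.64), Ccn5 (4.48), Slc1a3 (4.04), Alpl (−3.29) and Sp7 (−2.999). Without 213 Alpl and Sp7 were at −1.93 and −1.56, and without 182 Wif1 was at −7.61.

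Secondary tumours were compared with primary tumours. Ang, a secreted ribonuclease of the angiogenin family, was the 1 gene called, at 6.36 ± 0.35 (SD, n = 4) in secondary and 4.25 ± 0.38 (n = 15) in primary tumours (log2 difference 2.11, SE 0.216, limma adjusted p = 6.64e-06), and it was 7.79 to 8.26 in the osteoblast cultures. It was higher in all 4 secondary tumours than in any primary tumour. At an unadjusted p below 0.05, 1221 genes differed. With the tumour number as a block limma called 3 genes, Ang (1.93), Tsc22d3, which is induced by glucocorticoids (−2.31), and the transcription factor Zbtb16 (−3.80), each with an adjusted p of 0.0327. The adjusted p of Ang ran from 1.39e-08 to 0.0327 over the alternatives, except for treat, the random block, single probe sets and primary tumours of batch C, where none was recorded. Within batch B, which holds 7 primary and all secondary tumours, 9 genes were called: Ang (1.98), Eif2ak4 (1.00), Lims2 (1.02), Maneal (1.10) and Ttc22 (1.45) higher, and Zbtb16 (−3.53), Tsc22d3 (−2.17), Fkbp5 (−1.84) and Ptpru (−1.67) lower. With the batch as a term Ang alone was called (1.98). Apart from Ang, these genes were chosen after their values were seen.

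As lists, 6 groups differed between secondary and primary tumours while 0 of their members were called over all genes. The 15 skeletal muscle markers were lower (median −2.93, adjusted p = 2.1e-17, and adjusted p = 0.228 with an estimated correlation), 13 of them adjusted over the list alone. Mylpf was 3.78 ± 0.21 in secondary and 8.69 ± 2.76 in primary tumours (−4.91, adjusted p = 0.365), with Myh1 at −4.64, Myl1 at −4.32 and Tnnc2 at −4.30. The 6 MHC class II genes were higher (median 1.32, adjusted p = 3.59e-05, and adjusted p = 0.276 with an estimated correlation), 4 of them adjusted over the list alone, with H2-Ab1 at 1.48, H2-Aa at 1.40, H2-Eb1 at 1.34 and Cd74 at 1.30. The other lists had 0 members adjusted over the list alone. The 16 hypoxia and glycolysis genes were higher (median 0.53, adjusted p = 2.28e-05, and adjusted p = 0.448 with an estimated correlation), with the kinase Pdk1 at 0.85, Car9 at 0.85, Ankrd37 at 0.78 and Bnip3 at 0.69. The 19 mitosis genes were higher (median 0.54, adjusted p = 1.17e-05, and adjusted p = 0.694 with an estimated correlation), with Bub1 and Kif11 at 0.93, Nusap1 at 0.76 and Top2a at 0.75. The 21 S phase genes were higher (median 0.28, adjusted p = 0.00187, and adjusted p = 0.694 with an estimated correlation), with Cdc6 at 0.79, Uhrf1 at 0.72, Rbl1 at 0.72 and Ezh2 at 0.60. The 15 macrophage markers were lower (median −0.38, adjusted p = 0.00726, and adjusted p = 0.694 with an estimated correlation), with Cd163 at −0.72, Lyz2 at −0.61, Mrc1 at −0.55 and C1qa at −0.51.

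With the tumour number as a block the skeletal muscle (median −3.36), hypoxia (0.85) and mitosis (0.19) lists passed, and the MHC class II (0.94), S phase (0.06) and macrophage (0.07, the opposite direction) lists did not. Within batch B all 6 lists of the comparison of secondary with primary tumours passed, with medians of −3.17 for skeletal muscle, 0.98 for MHC class II, 0.60 for hypoxia, 0.67 for mitosis, 0.28 for S phase and −0.37 for macrophage genes. In this batch the Gapdh 5′ to 3′ ratio was 0.839 to 1.08 in the secondary and 0.656 to 0.845 in the primary tumours, and it was higher in the secondary tumour in 4 of the 4 pairs of the same number. The mitosis (0.24) and S phase (0.01) lists did not pass without secondary tumour 29, nor the macrophage list without 66 (−0.21) or 94 (−0.08). Without 64 the macrophage and MHC class II medians were −0.66 and 0.77, and without 66 that of S phase 0.45. Against the primary tumours of batch C, which share no batch with the secondary tumours, 251 genes were called and the hypoxia (0.34) and S phase (0.29) lists did not pass. Among the 251 were Mylpf (−4.82), Myl1 (−4.13), Myh1 (−3.87), H2-Ab1 (1.84), H2-Aa (1.64), H2-Eb1 (1.63) and Cd74 (1.61). With fry and all primary tumours the macrophage, mitosis and S phase lists did not pass.

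Cell lines and secondary tumours were compared with each other. Of the measured markers, 13 of 15 macrophage, 5 of 6 MHC class II, 8 of 14 endothelial and 5 of 12 osteoblast identity genes fell in the lines, and 4 of 15 skeletal muscle genes rose. Actc1, an actin of developing muscle, rose from 3.95 ± 0.22 (SD, n = 4) to 9.34 ± 3.51 (n = 4), a log2 difference of 5.39 (SE 0.913, limma adjusted p = 0.000158). The lines differed widely in Actc1, with 7.02 without cell line 176, 4.45 without 179 and 4.65 without 182. Its SD was 0.22 to 0.55 in the other groups, which share the spread used by limma. The SE and p-value of Actc1 therefore understate the uncertainty that comes from the lines. The other largest rises were in Ankrd1 (5.31) and Tagln (5.18), both expressed in contractile cells, and the largest falls in Wif1 (−7.46, SE 0.826, adjusted p = 9.78e-07), Prg3, a proteoglycan gene (−6.54), and C1qa (−6.44). limma called 1697 genes, 615 higher and 1082 lower, and 1275 and 3531 when every kept probe set was tested. The share of higher calls was 36.2%, against 51.7% after quantile normalization and 53.1% after 75th percentile scaling, which moved the median difference of all genes from −0.07 to 0.07 and 0.08.

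Of 15 macrophage markers 13 fell in cell lines against secondary tumours, and 13 adjusted over the list alone (median −3.70, adjusted p = 7.63e-14, and adjusted p = 0.228 with an estimated correlation), with C1qc at −6.34, C1qb at −5.70 and Mrc1 at −4.50. Of 6 MHC class II genes 5 fell, and 5 adjusted over the list alone (median −4.34, adjusted p = 6.64e-06, and adjusted p = 0.228 with an estimated correlation), with Cd74 at −5.35, H2-Aa at −4.97, H2-Eb1 at −4.37 and H2-Ab1 at −4.30. Of 14 endothelial markers 8 fell over all genes and 9 adjusted over the list alone (median −1.78, adjusted p = 9.94e-07, and adjusted p = 0.413 with an estimated correlation), with Cdh5 at −4.54, Esam at −2.85, Pecam1 at −2.53 and Plvap at −2.38. For Pecam1, at the floor in all lines to the printed digits, the value is again in effect a bound. Of 12 osteoblast identity genes 5 fell over all genes and 6 adjusted over the list alone (median −1.27, adjusted p = 0.000436, and adjusted p = 0.448 with an estimated correlation), with Alpl at −2.96, Sp7 at −2.55 and Pth1r at −2.15, and Msx2 stood at −2.54 (0.0505). Secondary tumours had 5 osteoblast identity genes higher than osteoblasts (camera adjusted p = 0.116), and the lines had 1 lower (0.168). Of 15 skeletal muscle markers 4 rose, and 4 adjusted over the list alone (median 2.55, adjusted p = 0.0333, and adjusted p = 0.795 with an estimated correlation), with Mylpf at 5.18, Tnnc2 at 4.70 and Myl1 at 4.28, and Tnnt3, at the floor in all 4 secondary tumours, was at least 12.5-fold higher without passing (adjusted p = 0.0677).

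No batch holds both cell lines and secondary tumours. With the batch as a term, which rests on the primary tumours, 741 genes were called, 597 of them among the 1697. The list medians were then −3.76 for macrophage, −3.65 for MHC class II, −1.72 for endothelial, −0.79 for osteoblast identity and 2.17 for skeletal muscle genes, all still passing. Alpl (−1.98), Sp7 (−2.06), Mylpf (5.37), Tnnc2 (5.26) and Myl1 (4.69) lost their calls. The muscle list did not pass without cell line 179 (1.61) or 182 (1.82) or secondary tumour 29 (2.66), nor after quantile normalization (2.66) or 75th percentile scaling (2.70), with the floor at the 40th percentile (1.77) or with fry. That floor also ended the calls of Mylpf (4.02), Tnnc2 (3.66) and Myl1 (3.40), and no filter on dim probe sets those of Tnnc2 and Myl1. Mylpf was not called without 179 (4.17) or 182 (4.65), and Alpl not without 213 (−2.19). Without cell line 176 the muscle median was 3.25, with Mylpf at 6.64, Tnnc2 at 6.28 and Myl1 at 5.61, while Alpl was at −3.55, Sp7 at −3.38 (−1.95 without 213) and Prg3, then at the floor in the other lines, at a bound of −7.31. Without 182 Wif1 was at −8.06. Myl1 was not called without 179 (3.27), 182 (3.87), 213 (4.36) or secondary tumour 29 (4.24), 66 (4.19) or 94 (4.21), and Tnnc2 was not without 179 (3.63), 182 (4.16), 213 (4.74) or any 1 of the secondary tumours (4.69, and at least 4.72 without 64). Tnnt3 was called without cell line 176 (at least 4.86), and Msx2 without it (−2.92), secondary tumour 64 (−2.91) or primary tumour 330 (−2.54). Both were called with array weights and with only both groups in the fit, Tnnt3 with the floor at the 5th percentile, and Msx2 with that at the 40th (−2.29) and the filter at the 75th percentile.

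Cell lines and secondary tumours were set against the primary tumour of the same number by the correlation, across 12887 genes, of deviations from the group means. The 4 secondary tumours had a mean correlation of 0.404 with their own primary tumour, and each of the 4 was closer to it than to any of the other primary tumours. The one-sided exact permutation p was 3.05e-05, the smallest that 32760 assignments allow. Within batch B the mean was 0.476 (one-sided exact p = 0.00119 of 840 assignments). For the 3 cell lines with a numbered primary tumour the mean was 0.0518, 0 of 3 were closest to their own, and the one-sided exact p was 0.193 of 2730 assignments, or 0.149 of 336 within batch C. The gap between own and other primary tumours was 0.234 to 0.682 in the secondary tumours and 0.031 to 0.092 in the cell lines. The mean gap was 0.378 larger in the former (two-sided exact permutation p = 0.0571 of 35 splits, where 0.0286 is the smallest possible). The difference missed the threshold because another split gave at least as large an absolute difference, although the groups did not overlap.

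**Figure D3:**
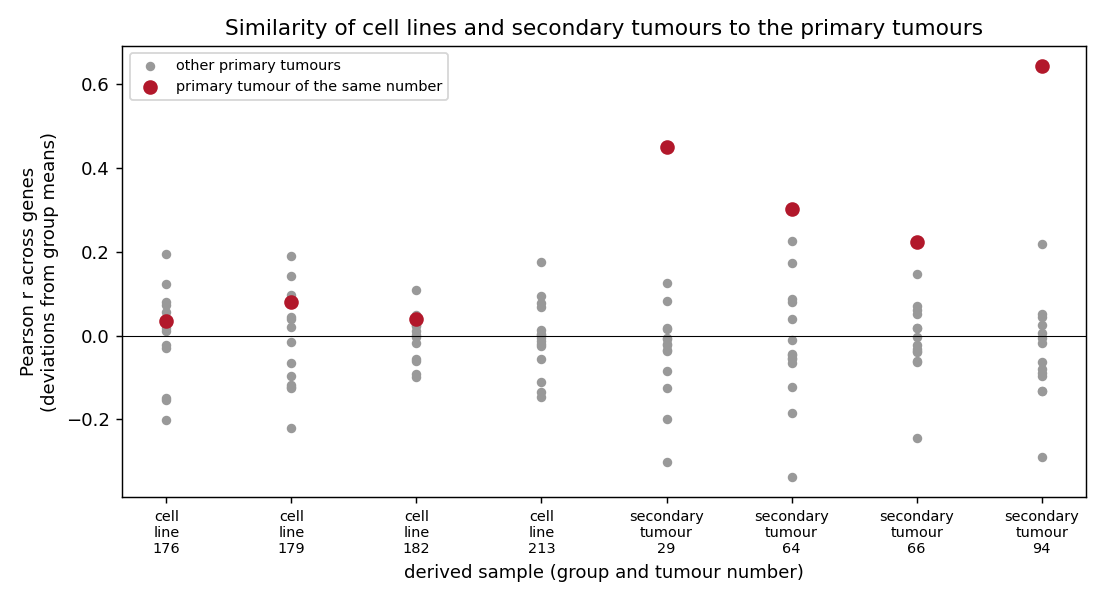
Pearson correlation across 12887 genes (vertical axis) between each cell line or secondary tumour and each primary tumour, as deviations from the group means. Red points are the primary tumour of the same number and grey points the others. The red point is the highest in each of the 4 secondary tumours, from 0.224 to 0.642, and in none of the 3 cell lines that have one, from 0.035 to 0.081.

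The remaining lists passed in no comparison, and their results are given for primary tumours against osteoblasts. In the Wnt pathway list of 13 genes Wif1, the transcription factor Lef1 (2.09) and Nkd2 (2.31) rose and the secreted regulators Sfrp1 (−4.75), Sfrp2 (−4.53) and Dkk3 (−1.80) fell (camera adjusted p = 0.669, with a median of 0.25 and a mean of −0.01). Of 20 osteosarcoma-associated genes 4 rose and 7 fell (adjusted p = 0.965, with a median of 0.08 and a mean of −0.04). Mycn, at the floor in the osteoblasts, was at least 8.40-fold higher, the chemokine receptor Cxcr4 rose by 2.14 and the transcription factor Twist1 by 1.45, and the growth factor genes Igf1 and Igf2 changed by −2.30 and −2.42. Of 9 osteoclast markers Ctsk (1.43) and Car2 (2.54) rose (adjusted p = 0.0775). Of 9 smooth muscle and pericyte markers Rgs5 rose (2.86) and 4 contractile genes fell, led by Cnn1 (−4.46) and Tagln (−4.20) (adjusted p = 0.31). Of 8 mineralisation and osteocyte genes Smpd3 rose (1.73) and Phex fell (−3.38) (adjusted p = 0.965). Of 10 immediate early genes Dusp1 rose (1.53) and Egr2 fell (−1.63) (adjusted p = 0.555). Of 7 neutrophil and myeloid precursor markers Mpo rose (1.33) and Prtn3 fell (−2.41) (adjusted p = 0.76). Of 4 sex-linked genes Kdm5d rose (1.08), while the list did not pass (camera adjusted p = 0.404). None of 3 T and NK cell (adjusted p = 0.965, with a median of −0.08 but an upward test), 2 B and plasma cell (0.778) or 3 erythroid markers (0.474) was called. In cell lines against osteoblasts 4 of the 8 mineralisation genes fell, Ibsp (−4.57), Ifitm5 (−3.05), Dmp1 (−5.21) and Phex (−3.85), also 4 adjusted over the list alone, while the list did not pass (adjusted p = 0.0968). The members named in this paragraph, apart from Wif1, were chosen after their values were seen. The same lists, adjusted over the list alone, gave 6 changed Wnt, 11 osteosarcoma-associated, 2 osteoclast, 5 smooth muscle, 1 mineralisation, 2 immediate early, 2 myeloid and 1 sex-linked gene.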

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

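Tests of the hybridisation batch for the differences between primary tumours, for the muscle genes and for the glucocorticoid-responsive genes, and the test of mature muscle fibres, were chosen only after the result was seen.

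In groups of 4 arrays a single array stood apart from the other 3 in 27 of 254 groups tested, where chance flags about 1 in 20 groups. In 10 of the 27 the other 3 arrays lay at the detection floor of 3.64, so that a small signal on 1 array was enough. All values are log2 intensities. Cell line 176 stood below the other lines in Hs6st2 (4.67, others 9.09 to 9.53), Slc1a3 (7.02, others 9.51 to 9.71), Eya4 (6.17, others 7.94 to 8.28), Lyz1 (3.64, others 5.03 to 5.31), Ifit1 (3.92, others 10.17 to 11.05) and Ankrd1 (7.91, others 9.35 to 9.61), and above them in Prg3 (6.72, others at the floor). Cell line 213 stood above the others in Cebpa (8.35, others 6.32 to 6.61), Adipoq (5.33) and Wfdc21 (4.03), the last pair with the others at the floor, and below them in Cd36 (3.64, others 4.28 to 4.35) and in the mean of the endothelial markers (5.44, others 5.48). Cell line 179 was low in Myc (7.66, others 8.32 to 8.40) and above the floor in C1qc (3.95). Cell line 182 was high in Cdh5 (4.70, others 3.64 to 3.68), low in Rbl1 (7.17, others 7.85 to 7.95) and alone above the floor in Pecam1, where the difference is lost in rounding (3.64).

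Among secondary tumours, number 64 alone was above the floor in Egfl6 (3.73), Pparg (3.85), Tnnc2 (3.74) and Eya4 (4.03), and stood above the others in Myl1 (4.58, others 3.72 to 3.86). Number 29 was high in the S phase gene Uhrf1 (9.20, others 8.39 to 8.49) and alone above the floor in Ankrd1 (4.19). Number 66, grown from a cell line, was high in Adm (6.27, others 5.28 to 5.39) and low in Col1a1 (13.71, others 13.92 to 13.96). Number 94 had the highest mean of the osteoblast identity genes (11.53, others 11.41 to 11.43). Outside the genes tested, the control probe set for 18S ribosomal RNA had an intensity of 197.02, 124.24, 615.12 and 141.01 in cell lines 176, 179, 182 and 213, above the 92.2 to 107 of the osteoblast cultures. It was 20.7 to 94.8 in primary and 18.2 to 23.8 in secondary tumours, so the lines lay above both tumour groups as well.

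Between the 7 primary tumours of hybridisation batch B and the 8 of batch C, 274 genes were called, 52 higher and 222 lower in batch C, among them Uty (−2.86), Bmp5 (−2.76), Snx22 (2.56) and Hnrnpu (−2.03), chosen after their values were seen. Chance is argued against, since 1 of 100 splits of these tumours, the real one, called as many, and the highest other called 51. The other splits were drawn at random from all possible ones. Skeletal muscle in the tumour pieces and the sex of the animals are argued against as the whole cause, because 250 and 154 of the 274 were still called with the muscle and the Y-linked score as a covariate. In the same genes cell lines (batch C) differed from secondary tumours (batch B) in the same direction (signed median 1.113, above all 100 random lists, the highest at 0.173), so the batch may be a cause. It cannot be told apart from the tumours themselves or from RNA quality, because tumour numbers run up to 119 in batch B and from 176 in batch C, and the Gapdh 5′ to 3′ ratio was 0.656 to 0.845 in the former and 0.909 to 1.03 in the latter.

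Muscle genes differed widely between the 4 cell lines: the mean of 10 genes of forming muscle was 4.63, 10.09, 9.24 and 8.05 in lines 176, 179, 182 and 213. Against osteoblasts 8 of the 10 rose, among them the myogenic factors Myod1 (4.28) and Myog (4.22). The SDs of Myod1 and Myog among the lines were 2.96 and 3.17. limma shares its spread between all groups, so these calls understate the uncertainty that comes from the lines. Of 7 genes of mature fibres 0 were called by limma in the lines against osteoblasts (0 at an unadjusted p below 0.05) and 4 rose in primary tumours. Mature fibres carried over from the tumours are argued against for lines 179, 182 and 213. Forming minus mature muscle was 4.422, 3.989 and 2.960 there and at most −0.24 in any primary tumour. Line 176, at −0.575, lay within the primary tumours. The mean was 4.703 higher in the lines (one-sided exact permutation p = 0.00103 of 3876), which is no independent support, since the lists were written from these arrays. Part of it comes from mature muscle genes, with a mean of 7.19 in primary tumours and 5.30 in the lines. The hybridisation batch is argued against by the primary tumours. There batch C exceeded batch B by 0.089 in the genes of forming muscle (one-sided exact permutation p = 0.254 of 6435), far less than the lines differ. No biological explanation was tested, since the labels give none that parts the lines, and a muscle-like state of some tumour cells or other cells in the cultures stay open. The lists were written after the muscle markers had been seen to differ.

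Zbtb16 and Tsc22d3, both induced by glucocorticoids, were called lower in secondary than in primary tumours with the tumour number as a block, also within batch B alone (−3.80 and −2.31), and within batch B without it (−3.53 and −2.17), but not against all 15 primary tumours (−2.65, limma adjusted p = 0.365, and −1.23, 0.555). Of 12 other such genes, listed after this was seen, limma called 0 against all primary tumours (2 at an unadjusted p below 0.05), and their mean differed by −0.613 there (two-sided exact permutation p = 0.128 of 3876) and by −0.967 within batch B (two-sided exact permutation p = 0.0152 of 330, which leaves out the pairing). In the 4 pairs of the same number, which share batch B, the secondary tumour was lower in 4, by a mean of −0.717 (SD 0.197). These 4 pairs allow a two-sided exact p of 0.125 at best. Within the pairs the hybridisation batch is argued against as the whole cause, since it does not differ there. This is no independent test, because Zbtb16 and Tsc22d3 were picked from fits on these same pairs and batch, and the 12 genes were listed afterwards. Skeletal muscle in the primary tumour pieces cannot be told apart from the group: with the muscle score as a covariate the difference was −1.07 (two-sided permutation p = 0.27 of 330), all secondary tumours had a low mean of the muscle markers (4.50 to 4.91), and primary tumour 119, with a muscle mean of 4.81 and the highest mean of the 12 genes on any array (9.95), goes against it but is 1 array. RNA quality, with a Gapdh 5′ to 3′ ratio higher in the secondary tumour of 4 of the 4 pairs, and differences between the host animals stay open.

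The number of genes called was set against other splits of the same arrays. Where more than 100 splits exist, 100 were run, the real one and others drawn at random. Of the splits run, only the real one called as many genes for primary tumours against osteoblasts (2378 genes, highest other split 890), cell lines against osteoblasts (1059, other 565) and secondary tumours against osteoblasts (2381, other 1254). The same held for cell lines against primary tumours (1514, other 725) and cell lines against secondary tumours (1697, other 102). The real split was 1 of 35 or of 100, the smallest share that the splits run allow, so chance is argued against but not excluded. The osteoblasts form a batch of their own, and no batch holds both cell lines and secondary tumours, so there the splits cannot part group from batch. For secondary against primary tumours chance is not argued against: 17 of 100 splits called at least the 1 gene of the real split. The highest called 343, which points to a structure of the samples. Among the 16 splits that part all 4 pairs of the same number, only the real one called a gene, and the highest other called 0 (limma, 1221 genes at an unadjusted p below 0.05 in the real split).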

How the results depend on the processing

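Results with primary tumours of 1 batch, with the batch as a term, with the block within batch B and without primary tumour 330 were chosen only after the data were seen. Of the named genes called, 123 kept direction and call in every alternative run and 25 lost the call somewhere. Of those not called, 25 kept their side, 16 were called somewhere and 8 changed sign. Of the 36 lists that passed, 3 passed throughout, 32 did not somewhere and 1 changed sign. An estimated correlation passed 3 lists and fry 55. Dim signal limits the fold of genes near the floor. The cause was not tested for the changes below, except that dropping the fold minimum, a stricter test or more probe sets changes counts by construction.

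In the order primary tumours, cell lines and secondary tumours against osteoblasts, then cell lines against primary tumours and against secondary tumours, limma called 6053, 2008, 6241, 4180 and 4806 when every kept probe set was tested, 5502, 1930, 4528, 4839 and 3911 genes without a fold minimum, and 1425, 373, 1103, 685 and 498 with treat. The batch as a term left 741 for cell lines against secondary tumours. Secondary against primary tumours gave 2 probe sets, 2 genes with only those groups in the model, 9 with primary tumours of batch B and 251 with those of batch C. With the tumour number as a replicate block it gave 3 genes, also within batch B. Cell lines share only a number with primary tumours, and that replicate block gave 648 genes, with 0 of 3 lines closest to their own number. As a random block the counts were 1563 and 1. The block changed no other call of secondary against primary tumours than those given with that comparison, where the macrophage median turned to 0.07 and Mrc1 to 0.027 in both block fits.

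Leaving out 1 array at a time gave 2123 to 2509, 778 to 1111, 2060 to 2441, 1361 to 1680 and 1554 to 1877 genes in the same order, 1 to 2 for secondary against primary tumours (2 without cell line 176, Ang and Ccn3), 33 to 41 lists, 498 to 685 genes shared by primary tumours and cell lines, and mean correlations of 0.313 to 0.453 for secondary tumours and 0.007 to 0.084 for cell lines. Among named genes, signs turned only in those that were not called. In cell lines against osteoblasts Cdkn1a was 0.157 after quantile normalization, 0.001 after 75th percentile scaling and 0.406 as the mean of its probe sets, and −0.644 to 0.354 with 1 array left out. Rb1 was 0.112 and 0.109 after these scalings and −0.504 to 0.252 with 1 array left out, Sp7 −1.328 to 0.108, and Col1a1 0.418 as the mean of its probe sets. In secondary tumours against osteoblasts Col1a1 was −0.047 after quantile normalization and −0.022 to 0.059 with 1 array left out, and Myc −0.047 to 0.283. Rb1 was −0.079 in primary tumours of batch C against osteoblasts. As the mean of its probe sets Cdh5 was −1.849 in cell lines against primary tumours, −2.133 in cell lines against secondary tumours and 1.363 in secondary tumours against osteoblasts. The same setting gave Ptx3 2.462 and H2-Ab1 −1.826 in cell lines against primary tumours, Csf1r 2.756 in secondary tumours against osteoblasts and Dcn −1.348 in cell lines against osteoblasts. With the floor at the 40th percentile Ang was 1.30 in secondary against primary tumours, Popdc3 2.30 in cell lines against osteoblasts, and Pecam1 −1.394 and the endothelial median −1.136 in cell lines against primary tumours, −1.114 and −1.026 against secondary tumours, with that median 0.828 in secondary tumours against osteoblasts. Quantile normalization gave a DNA damage response median of −0.317 in primary tumours against osteoblasts. In cell lines against osteoblasts the fibrous matrix median was −0.202 after it and −0.298 after 75th percentile scaling. These kept direction and call.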

Other observations

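The lists of positional genes were written, and the single arrays named here were chosen, only after the data were seen.

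Genes that mark position along the body differed between the osteoblast cultures and all tumour groups. Of 7 measured hindlimb and posterior Hox genes, 7 were lower in primary tumours, 7 in secondary tumours and 5 in cell lines against osteoblasts (limma). Hoxa10 differed by −5.01 in primary tumours, −5.24 in cell lines and −4.70 in secondary tumours, and Tbx4, a transcription factor of the hindlimb, by −4.24, −4.22 and −4.19. Hoxc10 differed by −4.55 in primary tumours and −4.48 in cell lines, and it lay at the floor in all 4 secondary tumours, where −4.56 is only a bound. Of 6 measured cranial and pharyngeal genes, 3 were higher in primary tumours, 5 in secondary tumours and 1 in cell lines. Tbx1 differed by 4.76 in primary and 5.81 in secondary tumours and Alx1, a transcription factor of the developing face, by 4.14 and 4.96, while in cell lines their differences of 1.87 (adjusted p = 0.294) and 2.21 (0.235) did not pass. Tbx1 and Alx1 lay at or just above the floor in the osteoblasts (mean 3.65 for each), so these differences are close to bounds. Pax3 rose by 2.36, 1.26 and 1.77 in primary tumours, cell lines and secondary tumours. The labels used here give no skeletal site for the tumours or the cultures.

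Sex-linked transcripts differed between groups and between partner arrays. The Y-linked genes Eif2s3y and Uty lay at the floor in all osteoblast cultures and cell lines and above it in all secondary tumours. Of 4 sex-linked genes limma called 3 higher in secondary tumours against osteoblasts and 3 lower in cell lines against secondary tumours. Neither list test passed (camera adjusted p = 0.287 and 0.292). In these comparisons sex-linked signal cannot be parted from the group. Cell line 176 had the Y-linked genes Eif2s3y and Uty at the floor and Xist, which is expressed from an inactive X chromosome, at 8.20, where primary tumour 176 had Eif2s3y at 6.58, Uty at 6.29 and Xist at 5.62. Secondary tumour 64 had Eif2s3y at 5.04 and Uty at 5.16 beside Xist at 12.98, where primary tumour 64 had both Y-linked genes at the floor and Xist at 13.04. Primary tumour 330 was low in the osteoblast genes Alpl (7.42), Sp7 (6.86) and Ibsp (4.73) and in Wif1 (7.38). A code in the labels of the secondary tumours was not interpreted, genotypes were not used here, and the Rb1 probe set does not tell whether a part of the gene is missing.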
